A study of Rattus norvegicus with 18 samples.

How the data were processed

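Bacterial communities of rat intestinal contents, also described as stool in the labels, were profiled by sequencing of the 16S rRNA gene, the ribosomal marker gene used to tell bacteria apart. Per the labels' protocols, DNA was extracted, variable regions of the gene were amplified with barcoded primers, and libraries were made with an Illumina TruSeq Nano kit. The samples fall into 3 groups of 6: untreated control rats, model rats with induced radiation enteritis, and a TG group that received a therapeutic intervention. The expansion of TG is not given in the sources used here. All samples carry the same batch label, and the series text describes the replicates as biological, with no animal named per sample. All groups have 6 samples analysed here.

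The deposited count table holds whole read counts of 8405 sequence features in 18 samples, exported from a BIOM table per the file headers. Per the labels of the series, reads were denoised and clustered before annotation. The denoiser, its version, the trimming, the chimera removal and any filter are not given in the sources used here. The counts were not rarefied by the authors, since sample totals differ from 23894 to 40575. How denoising and clustering treat near-identical templates decides how many features an organism yields, so numbers of features depend on those steps.

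A deposited taxonomy table names 10371 amplicon sequence variants (ASVs) and gives each assignment a confidence, a fraction per the file headers. The lowest confidence was 0.700 and the median was 0.991. Its identifiers are ASV numbers, while the count table uses hexadecimal identifiers. The 2 tables share 0 identifiers, and the files do not pair them. No feature was therefore given a taxon, and neither row order nor abundance was used to guess one. Genus calls, phylum shares, the shares of 10 fixed taxon lists and the planned count of genera with opposite changes were not run. The taxonomy was used only as a catalogue, by counting ASVs per name. A list member was matched at genus rank without prefixes, brackets and letter suffixes; Muribaculaceae and Desulfovibrionaceae, listed as families, matched ASVs of those families with no genus assigned. The lists were butyrate producers, lactobacilli and bifidobacteria, facultative anaerobes, mucin users, other Bacteroidales, sulfate and sulfite reducers, small-intestinal taxa, oral taxa, reagent and environmental taxa, and plant and host organelles.

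Features with at least 10 counts in at least 4 samples were tested, 431 in all, holding 83.4% of counts. Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors, glmQLFit and glmQLFTest over all 18 samples, and Benjamini-Hochberg adjusted p under 0.05 counted as a call. Features named in the text followed a rule: among calls with a mean share of at least 0.1% in either group, the 3 with the largest rise and the 3 with the largest fall by log2 fold change. Features are given by their abundance rank over all samples, with at most 2 identifiers per direction. A fold against a group without counts was computed against a floor of 3 counts over that whole group and is a lower bound. Intervals and floors cover counting error only, because amplified reads without molecular identifiers are not independent molecules. A share of 0 in a single library allows up to 0.0126% in the shallowest and 0.00739% in the deepest library.

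Observed features and the Shannon index (base 2, in bits) were means of 20 seeded rarefactions to 23894 counts. Bray-Curtis distances were computed on relative abundances, and groups were compared by permutational analysis of variance (PERMANOVA) with its R2, the share of squared distance between groups. These values were tested with exact two-sided permutation tests over all 924 splits of 12 samples (R2 is one-sided by nature), adjusted over the 3 comparisons. The smallest two-sided p this design allows is 0.00216. The spread of samples around their group centre was tested in the same way. Profile groups were defined after seeing the data. Tested features were joined by average linkage where the square roots of their shares correlated at 0.9 or more over the 18 samples, giving 314 groups. The 10 most abundant were tested in 3 comparisons, 30 tests adjusted together, also in each other setting.

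The edgeR procedure was tested on simulated data made from the 431 features for model against control. At a 64-fold change 76 of 200 changed features were recovered with 11 false calls, and at an 8-fold change 0 of 200 were recovered. Simulated unchanged groups gave 0 calls in 20 simulations. Each simulated feature was drawn independently of the others, while many features of the data moved together, so chance can spread wider in the data. The exact permutation test gave p under 0.05 in 4.6% of 500 null simulations. PERMANOVA R2 was checked against vegan 2.7.1. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

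The comparisons, tests, naming rule, taxon lists and main alternatives were fixed before the data were examined. Those alternatives were RLE factors, library totals alone, DESeq2 1.42.0 with poscounts size factors, no count filter, a filter of 50 counts in 6 samples, the fit on 2 groups, a replicate block, other rarefactions and distances, and leaving out each sample. Added after seeing the data were TMMwsp factors, profile groups summed, other correlation minimums, centred log-ratio values of features (0.5 counts added) with an exact permutation test, and a run without the 3 libraries holding under 300 features.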

Results

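The 18 libraries hold 594034 counts of 8405 bacterial sequence features. Totals per sample were 37208 ± 2717 (SD, n = 6) in control, 32293 ± 808 (SD, n = 6) in model and 29504 ± 5996 (SD, n = 6) in TG. Of all features, 7348 (87.4%) were seen in a single sample and 19 were seen in all 18. No pair of libraries was as close as repeated draws of reads from the same community. The closest pair, control 2 and control 4, had a Bray-Curtis distance of 0.265, against at most 0.0509 in 200 draws of sampling noise. Those draws cover counting noise only, so a repeated extraction or amplification of the same material is not excluded. Each printed feature is a sequence feature without a taxon, because the count and taxonomy tables use different identifiers.

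The taxonomy table is described as a catalogue of named ASVs, without their abundance in any group. Whether it comes from the same denoising run as the count table is not given in the sources used here, so its numbers describe that table and not the 18 libraries. Firmicutes_A, which holds the clostridia, made up 4688 of 10371 ASVs, Firmicutes_D, which holds the bacilli, 2661, and Bacteroidota 1863. The leading families were Lachnospiraceae, anaerobes that ferment fibre, with 2266 ASVs, Lactobacillaceae, lactic acid producers, with 1775, and Muribaculaceae, common in rodent guts, with 1556. Among genera, placeholder names included, Ligilactobacillus had 750 ASVs, Lactobacillus 661, CAG-485 314, Limosilactobacillus 274, Bifidobacterium 222, Blautia_A 213, and Allobaculum and CAG-873 195 each. A genus was not assigned for 3171 ASVs (30.6%).

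Among the fixed lists, lactobacilli and bifidobacteria covered 1907 ASVs, other Bacteroidales 946, of which 537 were Muribaculaceae with no genus assigned, and butyrate producers 187, of which 128 were Eubacterium. Facultative anaerobes covered 136 ASVs, led by Streptococcus with 59 and Corynebacterium with 41, and Escherichia and Klebsiella had 1 ASV each. Oral taxa covered 76 ASVs, 59 of them Streptococcus, a genus in both lists. Mucin users covered 55 ASVs, including 35 of Bacteroides and 4 of Akkermansia. Sulfate and sulfite reducers covered 49, of which 5 were Desulfovibrionaceae with no genus assigned, small-intestinal taxa 28, reagent and environmental taxa 19, and plant and host organelles 0. These numbers count sequence variants, not cells or reads.

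**Figure D1:**
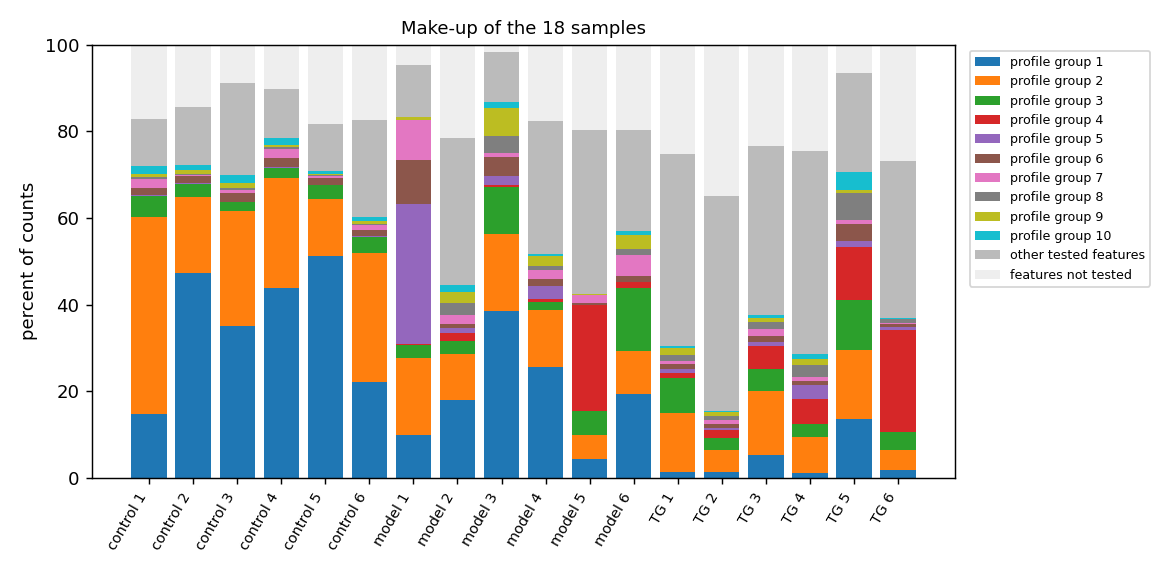
Stacked bars give the percent of counts (vertical axis, 0 to 100) of each of the 18 samples held by the 10 most abundant profile groups, the other tested features and features not tested. Profile groups 1 and 2 held 62.0% of control counts on average, 31.8% of model counts and 14.4% of TG counts.

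The comparison of model with control asks how community composition and diversity differed after disease induction. Control communities were dominated by 2 profile groups, sets of 9 and 7 features whose shares rose and fell together over the samples. Together they held 62.0% ± 5.88 (SD, n = 6) of counts in control and 31.8% ± 15.2 (SD, n = 6) in model, lower in model with an exact permutation p of 0.00433 (adjusted p = 0.00649). A further set, profile group 4 with 8 features, held 4.82% ± 9.64 (SD, n = 6) in model and 0.00789% ± 0.0193 (SD, n = 6) in control, where a single library had any count of it, and all 6 model libraries lay above the control median (exact permutation p = 0.00216, adjusted p = 0.0130 over 30 tests). Model 5 alone held 24.5% of its counts in that set, and the other model libraries held 0.189% to 1.90%. Without model 5 the difference fell from 4.81 to 0.886 percentage points (adjusted p = 0.0130), and without any 1 of the 6 control libraries it stayed at 4.81 or 4.82 but did not pass (adjusted p = 0.411 to 0.447). Each model library held more of that set than any control library, of which control 1 was highest with 0.0473%. With unequal group sizes, splits that put model 5 in the smaller group can exceed the observed difference of means. That loss therefore does not show dependence on any control library.

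Profile group 1 taken alone held 35.7% ± 14.6 (SD, n = 6) in control and 19.3% ± 12.02 (SD, n = 6) in model, a difference that did not pass (exact permutation p = 0.0628, adjusted p = 0.139). For profile group 2 the values were 26.3% ± 11.3 and 12.5% ± 4.80 (SD, n = 6 each), with an exact permutation p of 0.0173 and an adjusted p of 0.0649. Profile group 5, with 6 features, averaged 6.50% ± 12.7 (SD, n = 6) in model and 0.124% ± 0.0725 (SD, n = 6) in control, which did not pass after adjustment (exact permutation p = 0.0281, adjusted p = 0.0844). Model 1 held 32.4% of its counts in that group, and the other model libraries held 0.110% to 3.07%. Without model 1 the difference was 1.21 in place of 6.38 percentage points (adjusted p = 0.0703). The difference passed without model 5 (adjusted p = 0.0295) or model 6 (adjusted p = 0.0186), and that of profile group 2 passed without control 5 (adjusted p = 0.0390).

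At the level of single features, edgeR called 115 of 431 between model and control, 103 higher and 12 lower in model. The 103 higher features fell into 64 profile groups, 91 of them had no count in any control library, and together the 103 held 20.5% of model counts and 0.276% of control counts on average. They included members of profile group 4, at 24.5% of counts in model 5, and of profile group 5, at 32.4% in model 1. The model mean thus leans on those libraries, and it is not the share of each model library. The feature with the largest rise, 2eb0317b744004410680039ca426a1c1 (abundance rank 13, a member of profile group 4), held 1.22% ± 2.36 (SD, n = 6) of model counts and was seen in all 6 model libraries. It had 0 of 223249 control counts, so it was at least 897-fold higher in model (edgeR adjusted p = 1.98e-13). The features of rank 20 and rank 19, from the same profile group, were at least 721-fold and 691-fold higher. Model 5 carried these limits, which without it were 188-fold, 128-fold and 121-fold. Only 1 lower feature met the naming rule, that of rank 180, with 0.137% ± 0.0878 (SD, n = 6) in control and 0 counts in model, at least 88.8-fold lower (edgeR adjusted p = 0.0312). Its call ended without control 2 (adjusted p = 0.0616), without control 4 (adjusted p = 0.0554), without the count filter (adjusted p = 0.137) and with the replicate block (adjusted p = 0.161).

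The number of calls rested on every control library. Without control 1, 2, 3, 4, 5 or 6 it was 26, 22, 30, 23, 23 and 31, without model 5 it was 72, and 20 of the 115 calls had an adjusted p under 0.01. An exact permutation test on centred log-ratio values, added after seeing the data, called 0 features, with 86 at an unadjusted p under 0.05. Its smallest p is 0.00216, so after adjustment it can call none unless many features reach or come near that value. The same test called 61 features in TG against control, so that floor alone does not prevent calls. In model against control too few features came that low. The test thus does not back the edgeR calls, nor does it, on another scale, show them to be false. The median log2 fold change of all tested features was 0.77 in this comparison, 0.27 in TG against model and 1.28 in TG against control, and with RLE factors it was 1.33, 0.78 and 2.44. Those medians were not subtracted, so the log2 fold changes and numbers of higher and lower calls printed here still contain them. The fold limits were computed from counts over library totals, without such factors.

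**Figure D2:**
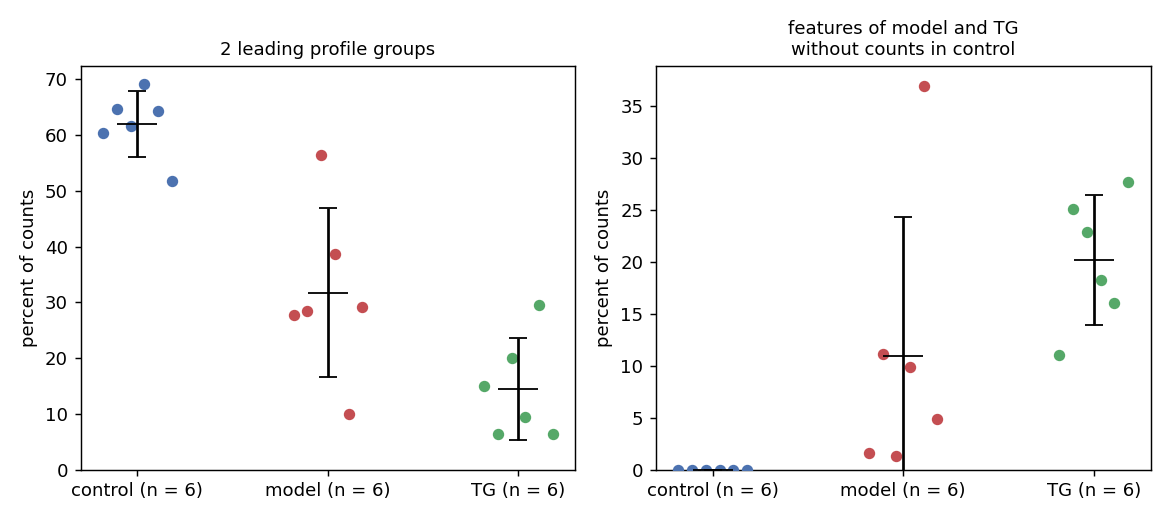
Percent of counts (vertical axes) held by the 2 leading profile groups (left) and by the 110 tested features seen in model and TG libraries but in no control library (right). Points are samples, and bars give the mean and SD of 6 samples. Every control sample had 51.8% or more in the leading groups, and TG samples had 29.5% or less.

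Whole communities differed between model and control. The group accounted for an R2 of 0.208 of the squared Bray-Curtis distances (exact permutation p = 0.00433, adjusted p = 0.00649). Model samples were also more scattered, with a mean distance to their group centre of 0.393 against 0.260 in control (exact permutation p = 0.0216, adjusted p = 0.0325), and the R2 test also responds to such a difference in spread. Observed features at equal depth were 634 ± 322 (SD, n = 6) in model and 565 ± 99.2 (SD, n = 6) in control (exact permutation p = 0.626). That difference of 68.2 was 40.7 without control 4 and 140, 4.10, 156, 19.3 and 33.9 without model 1, 2, 3, 4 and 6. The Shannon index was 6.77 ± 1.17 (SD, n = 6) in model and 6.00 ± 0.384 (SD, n = 6) in control (exact permutation p = 0.173). Neither diversity difference passed the threshold. Model 1 and model 3 had 273 and 195 features at equal depth, below the lowest control library at 428.

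The comparison of TG with model asks how communities differed after treatment. The 2 leading profile groups held 14.4% ± 9.09 (SD, n = 6) of counts in TG and 31.8% ± 15.2 (SD, n = 6) in model, farther from the 62.0% of control. Their sum was lower in TG with an exact permutation p of 0.0346 (adjusted p = 0.0346). That call ended without model 3, model 4, TG 2, TG 4 or TG 6, with adjusted p of 0.0671, 0.0541, 0.0714, 0.0671 and 0.0714. Profile group 1 held 4.08% ± 4.88 (SD, n = 6) in TG and 19.3% ± 12.02 in model, with all 6 TG libraries below the model median (exact permutation p = 0.0195, adjusted p = 0.0649). Profile group 2 was at 10.4% ± 5.03 (SD, n = 6) in TG and 12.5% in model, a difference of -2.14 percentage points that did not pass (exact permutation p = 0.459; -3.50 to -0.991 with 1 library left out). Profile group 7, a pair of features, fell from 3.47% ± 3.10 to 0.870% ± 0.385 (SD, n = 6 each), with 6 of 6 TG libraries below the model median (exact permutation p = 0.00433, adjusted p = 0.0216); its control value was 1.18% ± 0.777 (SD, n = 6). The fall of profile group 7 did not pass without any 1 of the 6 TG libraries (adjusted p = 0.0909 to 0.142), and without model 1 it was 1.45 in place of 2.60 percentage points (adjusted p = 0.0325). Leaving out a TG library also makes the group sizes unequal, which can raise the p of this test of means. That of profile group 1 passed without model 1 (adjusted p = 0.0361), model 5 (adjusted p = 0.0260) or TG 5 (adjusted p = 0.0464).

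edgeR called 6 of 431 features between TG and model, all lower in TG and all from profile group 1. These 6 held 33.8% of control counts, 18.3% of model counts and 3.90% of TG counts. The largest fall was that of 59c5bd27fd9beada774d5dc518d24534 (rank 21), at 0.663% ± 0.475 (SD, n = 6) in model and 0.0209% ± 0.0513 (SD, n = 6) in TG, where 1 of 6 libraries had any count (log2 fold change -4.74, SE 1.17, edgeR adjusted p = 0.0195). Its partner of rank 22 had a log2 fold change of -4.61 and the feature of rank 6 one of -2.05. TG 5 held all TG counts of the features of rank 21 and rank 22, and without it they were at least 304-fold and 302-fold lower in TG, while that of rank 6 had a log2 fold change of -2.84. With 6 calls by edgeR and 10 by DESeq2 in TG against model, 0 features were also called in model against control with the opposite direction. The exact test on centred log-ratio values called none in either comparison, and it can call none unless many features reach or come near its smallest p. At an unadjusted p under 0.05 in both comparisons, which share the model libraries and so favour opposite signs, 15 of 19 features by edgeR, 8 of 8 by DESeq2 and 2 of 11 by the exact test had opposite signs. In 20 simulations of unchanged groups edgeR gave 21.5 such features on average (11 to 31), each with opposite signs, a range that holds the observed number. The simulated features were drawn independently of each other, so that range may be too narrow. At an unadjusted p under 0.05, edgeR listed 44 features for TG against model.

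The 6 calls were lost with RLE factors and with a fit on TG and model alone, with 0 calls each. They were also 0 without model 4, TG 1, TG 2, TG 4 or TG 6, and 2 without control 6, model 2, model 3 or model 6.

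The R2 of the Bray-Curtis distances was 0.145 between TG and model (exact permutation p = 0.0649), which did not pass, and the spread around the group centres was 0.402 in TG and 0.393 in model (exact permutation p = 0.823). Without model 5 the R2 was 0.224 (exact permutation p = 0.00649), and without TG 5 it was 0.188 (exact permutation p = 0.0238). The mean Bray-Curtis distance to the 6 control samples was 0.736 ± 0.0931 (SD, n = 6) for TG and 0.583 ± 0.141 (SD, n = 6) for model. TG samples thus lay 0.153 farther from control on average, a difference just short of the threshold (exact permutation p = 0.0541). It passed without control 1 (0.161, exact permutation p = 0.0498), control 3 (0.153, exact permutation p = 0.0498), model 5 (0.199, exact permutation p = 0.00866) or TG 5 (0.180, exact permutation p = 0.0346). Among control samples the same distance was 0.402 ± 0.0530 (SD, n = 6).

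**Figure D3:**
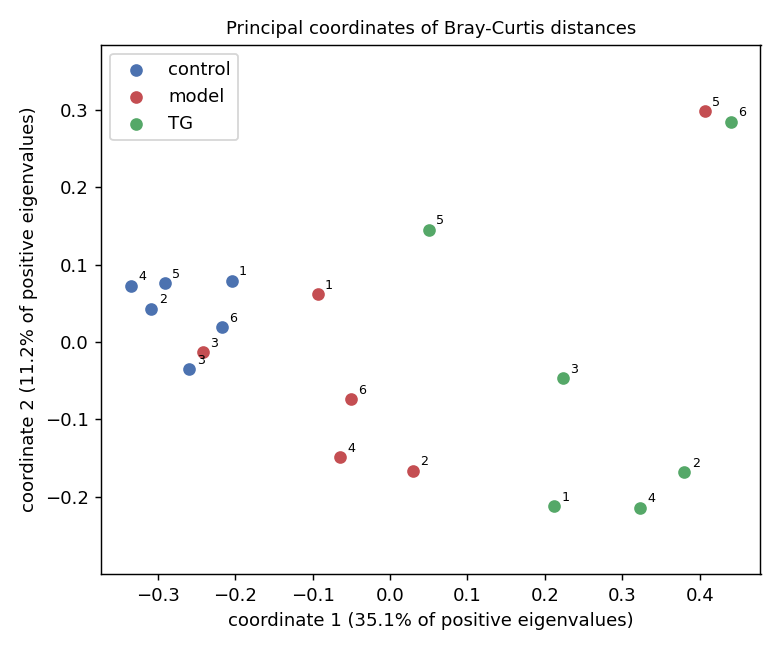
Principal coordinates of the Bray-Curtis distances of 18 samples, with coordinate 1 (35.1% of the positive eigenvalues) on the horizontal and coordinate 2 (11.2%) on the vertical axis. Points are samples, labelled by replicate number; the 6 control samples sit together at the left, and model 5 lies beside TG 6.

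Diversity did not differ past the threshold between TG and model. Observed features were 826 ± 282 (SD, n = 6) in TG (exact permutation p = 0.229), 192 above model, and 120, 104 and 303 above it without model 1, model 3 and TG 5. The Shannon index was 7.86 ± 0.895 (SD, n = 6), 1.09 above model (exact permutation p = 0.117, adjusted p = 0.173). TG 5 had the lowest values of its group, 271 features and a Shannon index of 6.14. Without TG 5 the difference in the Shannon index was 1.43 (exact permutation p = 0.0173, adjusted p = 0.0260).

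The comparison of TG with control spans disease induction and treatment together, and it held the largest differences of the 3 comparisons in R2, calls and Shannon index. The 2 leading profile groups fell by 47.6 percentage points, from 62.0% to 14.4% (exact permutation p = 0.00216, the smallest possible; adjusted p = 0.00649). Profile group 1 fell from 35.7% to 4.08% (exact permutation p = 0.00216, adjusted p = 0.0130) and profile group 2 from 26.3% to 10.4% (exact permutation p = 0.00866, adjusted p = 0.0371), each with 6 of 6 TG libraries below the control median. Profile group 4 rose from 0.00789% to 8.29% ± 8.51, profile group 5 from 0.124% to 1.32% ± 1.05 and profile group 8, with 3 features, from 0.308% ± 0.161 to 2.34% ± 2.09 (SD, n = 6 each). For these 3 groups all 6 TG libraries exceeded the control median (exact permutation p = 0.00216, adjusted p = 0.0130 each). Without TG 6 the rise of profile group 4 was 5.22 in place of 8.28 percentage points, without TG 4 that of profile group 5 was 0.787 in place of 1.20, and without TG 5 that of profile group 8 was 1.22 in place of 2.03. The calls of profile groups 4 and 8 ended without any 1 control library, with rises of 8.28 to 8.29 and 1.99 to 2.07 percentage points (adjusted p = 0.0649 to 0.0835), and those of profile groups 1, 2 and 5 without control 1, 2, 3, 4 or 6 (adjusted p = 0.0519 to 0.0835). TG libraries held at least 0.996%, 0.452% and 0.718% in groups 4, 5 and 8. Control libraries held at most 0.0473%, 0.219% and 0.490% there. In group 1 TG libraries held at most 13.5% and control libraries at least 14.8%. Unequal group sizes can raise the p of this test of means, and the adjusted p also depends on the other tests. The losses for groups 1, 4, 5 and 8 therefore do not show dependence on any control library. The call of profile group 2 also ended without any 1 TG library (adjusted p = 0.0568 to 0.0835). Of the 30 tests on profile groups, 7 passed.

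edgeR called 159 of 431 features, 123 higher and 36 lower in TG. The 123 higher features held 28.4% of TG counts and 0.246% of control counts, fell into 77 profile groups, and 111 of them had no count in control. The 36 lower features held 62.1% of control counts and 13.8% of TG counts. The feature of rank 13 was at 1.94% ± 1.98 (SD, n = 6) in TG, at least 1525-fold above control (edgeR adjusted p = 5.21e-14). Next were 28f0a1dcb4405bdaa5d6a58af2cb9b00 (rank 19), at least 1361-fold higher with 1.74% ± 1.83 (SD, n = 6) in TG, and the feature of rank 20, at least 1276-fold higher. The largest falls under the naming rule were the features of rank 118, rank 200 and rank 180, with 0.192%, 0.107% and 0.137% of control counts and none in TG, at least 118-fold, 64.5-fold and 81.1-fold lower. They were seen in 4, 3 and 5 of the 6 control libraries, and their calls ended without the count filter (adjusted p = 0.0871 to 0.111) and with the replicate block (adjusted p = 0.0657 to 0.0756).

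With any single sample left out, 128 to 176 features were called. The calls numbered 27 without the count filter, 35 with the stricter filter, 90 with DESeq2 and 61 with the exact permutation test on centred log-ratio values. Of those 61, 32 were higher and 29 lower in TG, and the median of all tested features was 1.00 on that scale, which is centred per sample over all features.

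Calls of the 2 comparisons against control overlapped. Of 103 features higher in model and 123 higher in TG, 100 were the same. Lists of these lengths, taken by the smallest p, shared 66.1 features on average (58 to 74) in 20 simulations of unchanged groups against the same controls, where none passed the threshold, and 29.4 would be shared by independent lists, a value that leaves out the shared controls. The simulations drew each feature independently, while many features of the data moved together. Ranges from them may thus be too narrow, and they do not settle whether 100 exceeds chance. With 3 of the 6 control samples used for model and the other 3 for TG, 8 to 10 features were called higher in both over 20 such divisions, in which each comparison also had fewer samples. Of the lower features, 12 and 36 were called and 5 shared, within the 1 to 5 (mean 2.40) that lists of these lengths shared in the same simulations. With divided controls, model against control had 0 lower calls, so none could be shared. Among tested features, 110 were seen in model and TG libraries but in no control library. Another 19 were seen in control and model but not in TG, and 11 in control and TG but not in model. Features seen in 1 group only, which has fewer libraries to meet the count filter, were 5 for control, 2 for TG and 0 for model. The 110 held 10.9% ± 13.4 (SD, n = 6) of counts in model and 20.2% ± 6.22 (SD, n = 6) in TG, a difference that did not pass (exact permutation p = 0.149, adjusted p = 0.210). Model 5 alone held 36.9%, while the other model libraries held 1.31% to 11.1% and the TG libraries 11.04% to 27.7%. Without model 5 the model mean was 5.74% ± 4.57 (SD, n = 5) and the difference 14.4 in place of 9.24 percentage points (exact permutation p = 0.00649, adjusted p = 0.0130). A count of 0 over the control group allows each feature up to 0.00134% there.

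**Figure D4:**
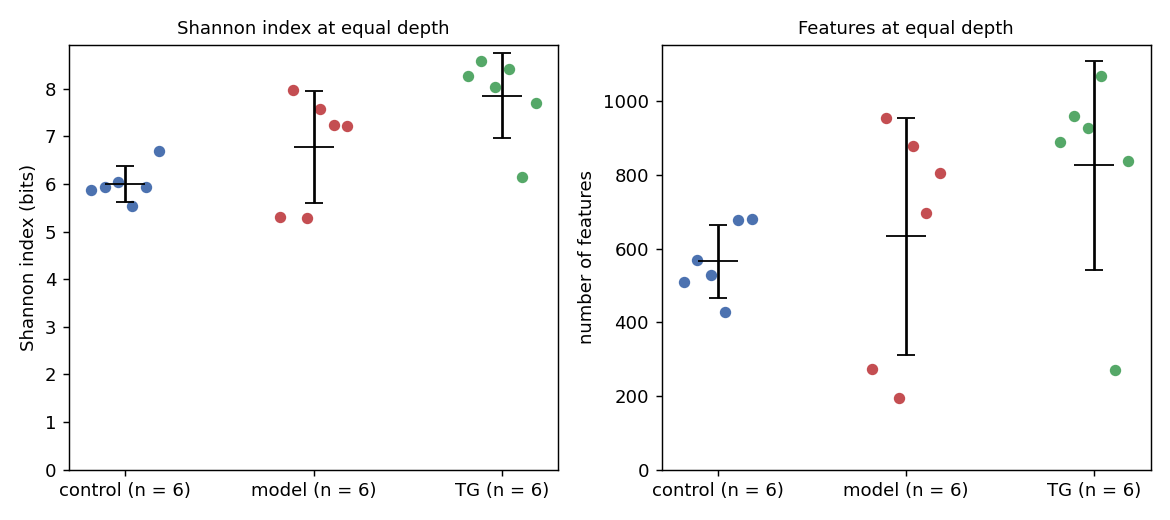
Shannon index in bits (left) and number of observed features (right) at an equal depth of 23894 counts. Points are samples, and bars give the mean and SD of 6 samples per group. TG 5, model 1 and model 3 are the 3 samples with 271, 273 and 195 features.

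Community structure and the Shannon index differed between TG and control. The R2 was 0.401 (exact permutation p = 0.00216, adjusted p = 0.00649), with a larger spread in TG (0.402) than in control (0.260; exact permutation p = 0.00433, adjusted p = 0.0130). The Shannon index was higher in TG by 1.86 bits (exact permutation p = 0.00433, adjusted p = 0.0130). With the library total as covariate that difference was 0.814 (SE 0.228, exact permutation p = 0.00866). Observed features were 826 against 565, a difference of 260 that did not pass (exact permutation p = 0.0649, adjusted p = 0.195). Without TG 5 it was 371 (exact permutation p = 0.00216, adjusted p = 0.00649). With features seen in 1 sample removed, it was 88.8, and the difference was 52.6 in place of 192 for TG and model and 36.2 in place of 68.2 for model and control.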

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

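The tests of depth given here were chosen after the libraries with few features had been seen; the test on features of 0.1% or more was written before its result. Over 15 measures and 3 groups, 45 sets of 6 samples were searched for a sample far from the others of its group, and 10 were found. Chance would give about 2.25 for normally distributed values. Many of the measures are skewed shares and several depend on each other, so an excess over chance is not shown. TG 5 accounted for 6 of the 10. Its 271 features at equal depth and Shannon index of 6.14 lay below the nearest other TG library (838 and 7.71). It also had the highest TG share of profile group 1 (13.5%, next 5.40%), group 6 (3.95%, next 1.39%), group 8 (6.36%, next 2.77%) and group 10 (4.07%, next 1.20%).

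Profile group 4 held 24.5% of the counts of model 5, against 1.90% in the next model library, and 0.0473% in control 1, against 0 in the other control libraries. Profile group 5 held 32.4% of the counts of model 1, with 3.07% next, and 3.37% in TG 4, with 1.29% next.

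TG 5, model 1 and model 3 share the low number of features. Lower depth is argued against: their totals were 40575, 32295 and 33342, and at equal depth the highest of the 3 had 273 features while the lowest of the other 15 libraries had 428. A loss of rare features alone is argued against as well, since they held 103, 72 and 69 features of 0.1% of counts or more, where the other libraries of their groups held at least 204 (TG) and 150 (model). No biological explanation was tested, because the labels do not set these libraries apart. A difference in sampling, in amplification or in the animals stays open.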

How the results depend on the processing

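The settings named as added and the profile groups were chosen after seeing the data. Without a count filter 20 features were called in model against control and 27 in TG against control; 50 counts in 6 samples gave 19 and 35, where 79 features were tested. The replicate block gave 20 and 50. DESeq2 gave 58, 10 (TG against model) and 90, with 135, 160 and 102 adjusted p-values missing. A fit on 2 groups gave 58 for model against control and 0 for TG against model, and RLE factors gave 0 for the latter. Of the added settings, summed profile groups gave 50, 1 and 92 calls among 314 groups, and centred log-ratio values with an exact permutation test gave 0, 0 and 61, with 86, 35 and 119 at an unadjusted p under 0.05. That exact test can call none unless many features reach or come near its smallest p, which held in TG against control only. Without the 3 libraries holding under 300 features, the difference of profile group 5 between TG and model turned from -5.18 to 0.180 percentage points, neither of which passed. For named features and profile groups 1, 2, 4, 5, 7 and 8, 139 values stayed on their side of the threshold, 12 lost a call and 2 gained one; with single libraries left out these numbers were 376, 66 and 8. Apart from fewer features tested or fewer samples, the cause was not tested.

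With single libraries left out, calls ranged from 22 to 132 (model against control) and from 0 to 7 (TG against model). For TG against control the difference in observed features ranged from 212 to 371. For TG against model the Shannon difference ranged from 0.794 to 1.43, R2 from 0.129 to 0.224, the difference in distance to control from 0.115 to 0.199, and that of the 2 leading profile groups from -21.7 to -12.4 percentage points.

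Replicate numbers did not pair the samples: correlations of same-numbered deviations ran from -0.281 to 0.130, 1 of 18 pairs exceeded 0.1, and 2 samples correlated best with their own number. With the replicate block the Shannon difference of TG and control stayed at 1.86 with an exact sign-flip p of 0.0313 (adjusted p = 0.0938). That p is the smallest this test allows with 6 pairs. After adjustment it can pass only where another comparison reaches it too, so this loss does not show dependence on the block. The block left 6 calls in TG against model and changed no other side of the threshold among distances and diversity. R2 for model and TG against control passed under all 6 other settings, but was lower, at 0.109 and 0.123, with Jaccard distances and, at 0.131 and 0.168, with Aitchison distances. Planned genus calls, phylum shares, taxon list shares, genus-level distances and diversity, and the count of genera with opposite changes were not run, because the files do not pair features with taxa; the last was made on features and gave 0, as it had to where TG against model had 0 calls. In the self-test 0 of 200 simulated 8-fold changes were recovered, while in the data the smallest called log2 fold change was -1.95 in TG against model and -1.55 in TG against control, so the self-test sets no detection limit for each feature.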

Other observations

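The tests of depth, of the paired features and of other sample splits were chosen after their results had been seen; the test without the 2 leading profile groups was written before. All 6 control libraries had another control library as their closest sample, and 4 of 6 did so in each of model and TG. Model 3 lay closest to control 4 (Bray-Curtis distance 0.321) and not to the nearest model library (0.445). Model 5 and TG 6 were closest to each other (0.496), while the nearest library of their own groups was at 0.717 and 0.656. TG 5 lay closest to model 3 (0.403). Of the 110 features absent from control, 15 were seen in all 6 TG libraries and 1 in all 6 model libraries.

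The Shannon index was higher in TG than in control by 1.86 bits. Depth as the whole cause is argued against, since with the library total as covariate the difference was 0.814 (SE 0.228, exact permutation p = 0.00866), 0.695 to 1.27 with 1 library left out (highest without TG 5; exact permutation p at most 0.0216). Depth as part of the cause stays open, because the slope of the index per 1000 counts was -0.135 (SE 0.0199) with all libraries and -0.0198 (SE 0.0449) without the 2 libraries of each group farthest from its median total. In that smaller set of 4 libraries per group the difference with the covariate was 1.98 (SE 0.453, exact permutation p = 0.0571). A candidate explanation is the dominance of the 2 leading profile groups in control. Without their features, at an equal depth of 12349 counts, the index was 7.93 ± 0.977 in TG and 7.84 ± 0.329 in control (SD, n = 6 each). That is a difference of 0.0903 (exact permutation p = 0.885). The groups were picked from the same data, and taking out features that dominate control tends to raise its index most. The smaller difference is therefore no independent support. Without those features model lay below control by 0.783 (exact permutation p = 0.307), in place of 0.768 above, and TG above model by 0.874 (exact permutation p = 0.271), in place of 1.09. The difference of TG and model passed neither with nor without these features, so whether the dominance accounts for it cannot be told.

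Abundant features came in near-identical pairs. Of the 50 most abundant tested features, 39 had a partner with a correlation over 0.95, and 0 did after shuffling within groups. In 14 mutual pairs the smaller total was 0.971 of the larger at the median, against 0.558 for random partners. A template split into several features would keep a fixed ratio, and separate taxa that rise and fall together would not. The chi-square of the ratio over samples, per degree of freedom, had a median of 2.79 (0.767 to 11.7), with 4 pairs over 5 and 5 pairs under 2, against 152 for random partners. The median lies between both predictions and single pairs fall on either side. The chi-square also assumes independent reads, which amplified reads are not, so these explanations cannot be told apart by it. The number of calls may count some organisms more than once: summing profile groups gave 50 calls in place of 115 for model against control.

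Of 462 splits of the samples of each comparison, 100 drawn ones were fitted for the feature calls. For TG against control 1 of 100 splits gave as many calls as the real 159, the real split itself, and the highest other gave 7. That argues against chance for the fit with all libraries. For TG against model 1 of 100 gave 6 or more, and the highest other gave 4. For model against control 1 of 100 gave as many as 115, with 99 in the highest other split. For both, the real split gave the most calls of those drawn, but by a narrow margin and only in the fit with all libraries. Chance is therefore not excluded for either. The 6 calls, all from 1 profile group, fell to 0 with RLE factors and with the fit on 2 groups. They also fell to 0 without model 4, TG 1, TG 2, TG 4 or TG 6. The 115 fell to 22 to 31 without any 1 control library. The exact test on centred log-ratio values gave 0 in both comparisons. It can call none unless many features reach or come near its smallest p, as they did in TG against control.

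Within groups, deeper libraries had a lower Shannon index at equal depth. Pearson's r was -0.850 in control (exact permutation p = 0.0181, adjusted p = 0.0438), -0.630 in model (exact permutation p = 0.189, adjusted p = 0.189) and -0.928 in TG (exact permutation p = 0.0292, adjusted p = 0.0438). Spearman's rho was -0.829 (exact permutation p = 0.0583), -0.714 (exact permutation p = 0.136) and -0.714 (exact permutation p = 0.136), adjusted p = 0.136 for each of the 3 groups. Without the 2 samples farthest from the median total, r was -0.196, 0.146 and -0.217, so the relation rests on those samples.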
